A study of Homo sapiens with 6 samples.

How the data were processed

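Poly(A)-selected, strand-specific RNA-seq was made from gelatin hydrogels in which human cells had been kept for 7 days. The 6 libraries fall into 2 groups of 3, as the labels give them. In the Tri-Culture group, endothelial cells of the umbilical vein (HUVEC), lung fibroblasts (NHLF) and the glioblastoma cell line U87-MG, all human, shared the same gel. In the Mixed group, RNA of gels holding U87-MG alone was combined with RNA of gels holding HUVEC and NHLF, in proportions set so that fibroblast RNA made up an equal fraction in both groups, per the labels' protocols. The labels name 3 replicates per group. They do not say whether each is a separate gel or a separate RNA mix, so the p-values measure the spread between these samples, which may be technical in part.

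The deposited values are raw counts of reads per gene, one table per library, and were not normalized. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Trimmomatic 0.36, STAR 2.5.3a, Subread 1.5.2 and edgeR 3.18.1 were used with genome build GRCh38.p10. Per the file headers, featureCounts of Subread 1.5.2 summed reads over exons per NCBI GeneID with the reverse-strand setting (2), so antisense genes are told apart. Reads with several best positions are left out under that program's default, and the headers show no option that would count them. The annotation used for counting also lists 2782 of the genes kept here on alternate or patch scaffolds, where reads can have a second, equal position. Among protein-coding genes, 557 of 1040 such genes (53.6%) had 0 counts in all libraries, against 2602 of 18287 (14.2%) of the others. RPL7A, RPS18 and NDUFS1, which proliferating human cells transcribe, are among those with 0 to 3 counts per library. A gene of that kind at or near 0 was therefore not read as silent, and HLA genes are not reported here. Members of gene families with near-identical copies can likewise lose reads.

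The tables hold 45393 GeneIDs. Symbols were attached for 42751 of them from NCBI's GRCh38.p14 gene table, used for names only; the 2642 others held at most 0.0735% of the counts of a library. Coordinates are those of the count tables (GRCh38.p10, first to last exon, 1-based). XIST, TSIX and the genes found on chromosome Y only (238 genes in all) were removed before the low-count filter and all tests, because the primary cells come from donors. Library totals before that removal ranged from 45841498 to 58567973 counts. In the library with the smallest scaled size 3 counts correspond to 0.0656 CPM after scaling, and such a floor covers counting error only.

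Tri-Culture was compared with Mixed by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust dispersion, TMM normalization, no replicate term) on the genes kept by filterByExpr with a minimum count of 10. That filter left 16080 genes. All tests are two-sided, a gene was called at a Benjamini-Hochberg adjusted p below 0.05, and adjusted p-values of single genes come from that test. Log2 fold changes are Tri-Culture over Mixed, given ± their standard error (SE). CPM values use TMM-scaled library sizes and are given as mean ± SD over the 3 libraries of a group. Levels of a gene list in a library are means of log2 CPM (prior count 2) relative to the mean of the Mixed libraries.

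The 27 gene lists were written before the data were examined: endothelial, fibroblast, lung mesenchyme, contractile and mural, glial and glioblastoma, epithelial and leukocyte markers, and genes of the 9p21 interval, the G1/S and G2/M phases, matrix proteases, collagens, matrix glycoproteins, angiogenesis, hypoxia and glycolysis, repair of temozolomide damage, drug efflux and detoxification, interferon response, inflammation, TGF-beta response, glioma stem cells and invasion, cholesterol synthesis, unfolded protein stress, p53 targets, immediate early and heat shock genes, ribosomal proteins and oxidative phosphorylation. Each was tested against all other genes with camera (limma 3.58.1, preset inter-gene correlation of 0.01), adjusted over the 27 lists. The same test with a correlation estimated from the data, and fry, which asks whether the members move on balance one way, were run beside it. Genes were named by a rule fixed at the same time: the 10 called genes with the largest change in each direction that have non-overlapping groups, a mean CPM of at least 5 in the higher group and an established symbol; up to 4 called members with the smallest p in each list; and a fixed set of 21 genes. Other list members in the report (among them TNFAIP3, IL6, SLC2A1, SLC2A3, GAPDH, INHBA and TBX5) were chosen after their values were seen. Some genes that the rule selects are not reported here.

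On simulated counts for the same 16080 genes and libraries, the test recovered 49% of 100 genes changed by 0.5 on the log2 scale and 65% of 100 genes changed by 1. At a mean CPM of 5 or more these shares were 71% and 96.7%. It called 16 of 15840 unchanged genes and gave no call the wrong sign. Only 240 genes were changed in the simulation, whereas 21.5% of the tested genes were called in the data. Genes were also drawn independently, with no shift shared within a library, so these rates need not hold for the data. The alternatives tried were DESeq2's size factors, library totals alone, no filter beyond 1 count in any library, a filter of CPM of at least 1 in 3 libraries, DESeq2's Wald test (version 1.42.0), the replicate number as a block, leaving out each library in turn and, added after seeing the data, leaving out genes on alternate scaffolds. Mitochondrial protein-coding genes were not analysed here.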

Results

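RNA was sequenced from hydrogels of methacrylamide-functionalized gelatin, 5 mm across and 1 mm thick, after 7 days in endothelial growth medium. Perivascular cells were seeded at 1000000 HUVEC and 2000000 NHLF per mL, and U87-MG, a human glioblastoma line, at 100000 per mL. HUVEC are primary endothelial cells of the umbilical vein and NHLF are primary lung fibroblasts. Total counts were 48272216, 54818282 and 58567973 in Tri-Culture replicates 1, 2 and 3, and 45841498, 57540239 and 46733800 in Mixed replicates 1, 2 and 3. All pairs of replicates differed by more than sampling noise. The title of the series names the purpose, which is to learn how signals from perivascular cells alter glioblastoma cells. The comparison of Tri-Culture with Mixed addresses this with the same 3 cell types in both groups, which shared a gel in Tri-Culture only. By the seeding densities, gels of U87-MG alone held far fewer cells per mL than Tri-Culture gels. Signals from the other cells can therefore not be told apart from a higher total cell density. The fibroblast RNA fraction alone was set equal, so the shares of endothelial and U87-MG RNA can differ between the groups. Every library holds RNA of all 3 cell types, so a change in a gene cannot be assigned to one of them from these counts.

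In cells that shared a gel, some hypoxia and glycolysis, inflammatory, matrix protease and collagen genes were higher, and some cell cycle, DNA repair and detoxification genes were lower. Camera with its preset correlation called 9 gene lists higher and 6 lower, while 0 were called either way with an estimated correlation and fry called 1 each way. Of 16080 genes tested, 1774 were higher and 1681 lower in Tri-Culture by edgeR's quasi-likelihood test, 21.5% of the total. Most changes were small: the median absolute log2 fold change of the called genes was 0.44, and a fold of at least 2 was reached by 245 higher and 171 lower genes. The groups did not overlap in 40.1% of the tested genes, where chance gives 10%. The calls were split evenly under TMM (51.3% higher), but library totals alone shifted all genes by −0.11 (median log2) and gave 1068 higher and 3344 lower genes (24.2% higher), and 186 higher and 242 lower genes at a fold of at least 2. Without Mixed replicate 2 the counts were 742 higher and 695 lower, without Tri-Culture replicate 3 they were 1011 and 859, and the genes higher by a fold of at least 2 numbered 162 without Tri-Culture replicate 1, 110 without Mixed replicate 2 and 416 without Mixed replicate 3. On the first principal component, which held 48% of the variance, the Tri-Culture libraries lay at −35.2, −25.8 and −28, Mixed replicates 1 and 2 at 49.3 and 31.8, and Mixed replicate 3 at 7.8.

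The largest rises included cytokine, protease and transcription factor genes. IL24, a cytokine of the IL-10 family (GeneID 11009, chromosome 1, 206897404 to 206904139, GRCh38.p10), rose from 3.75 ± 1.09 CPM in Mixed to 21.7 ± 9.69 CPM in Tri-Culture (SD, n = 3 each), a log2 fold change of 2.53 ± 0.45. It was followed by SLAMF8, an immune cell surface receptor (2.06 ± 0.20), and NR4A3, an orphan nuclear receptor induced by many stimuli (1.99 ± 0.17). MMP9, the type IV collagenase gelatinase B (GeneID 4318, chromosome 20, 46008908 to 46016561), rose by 1.83 ± 0.23 on the log2 scale, from 2.55 ± 1.01 to 9.03 ± 0.61 CPM. The other genes of the top 10 were EGLN3, an oxygen-sensing hydroxylase (1.68 ± 0.35), GDNF, a neurotrophic factor (1.66 ± 0.18), the transcription factor FOXQ1 (1.65 ± 0.11), G0S2, an inhibitor of triglyceride lipase (1.58 ± 0.26), CXCL8, the neutrophil chemokine interleukin 8 (1.57 ± 0.31), and IL1RL1, the receptor of interleukin 33 (1.55 ± 0.24). Of these calls 4 were lost when a library was left out, with adjusted p up to 0.0758 for IL24, 0.113 for EGLN3, 0.0603 for G0S2 and 0.0951 for CXCL8, while their log2 fold changes stayed at 1.36 or more. With no low-count filter IL24 (adjusted p = 0.052), EGLN3 (0.0684) and CXCL8 (0.0586) lost their calls, as EGLN3 (0.0786) and CXCL8 (0.0788) did with the replicate number as a block.

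Large falls were seen in genes of diverse function. GALNT9, a glycosyltransferase that starts mucin-type O-glycans (GeneID 50614, chromosome 12, 132195829 to 132329364), fell from 9.86 ± 1.55 CPM to 1.34 ± 0.57 CPM, a log2 fold change of −2.87 ± 0.25. The keratin KRT80 changed by −2.46 ± 0.24 and NMNAT2, an enzyme of NAD synthesis in neurons, by −2.03 ± 0.14. SP140 (−2.00 ± 0.22), KCTD4 (−1.96 ± 0.21), the kinase PAK3 (−1.91 ± 0.26), the lipid phosphatase PLPP4 (−1.89 ± 0.21), the vesicle GTPase RAB27B (−1.72 ± 0.15) and TMT1B (−1.71 ± 0.20) fell as well. CHI3L1, a secreted glycoprotein linked to mesenchymal glioma (GeneID 1116, chromosome 1, 203178931 to 203186794), fell from 10.3 ± 1.70 to 3.01 ± 1.141 CPM, a log2 fold change of −1.78 ± 0.24. All 10 genes kept their calls in each alternative run.

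**Figure D1:**
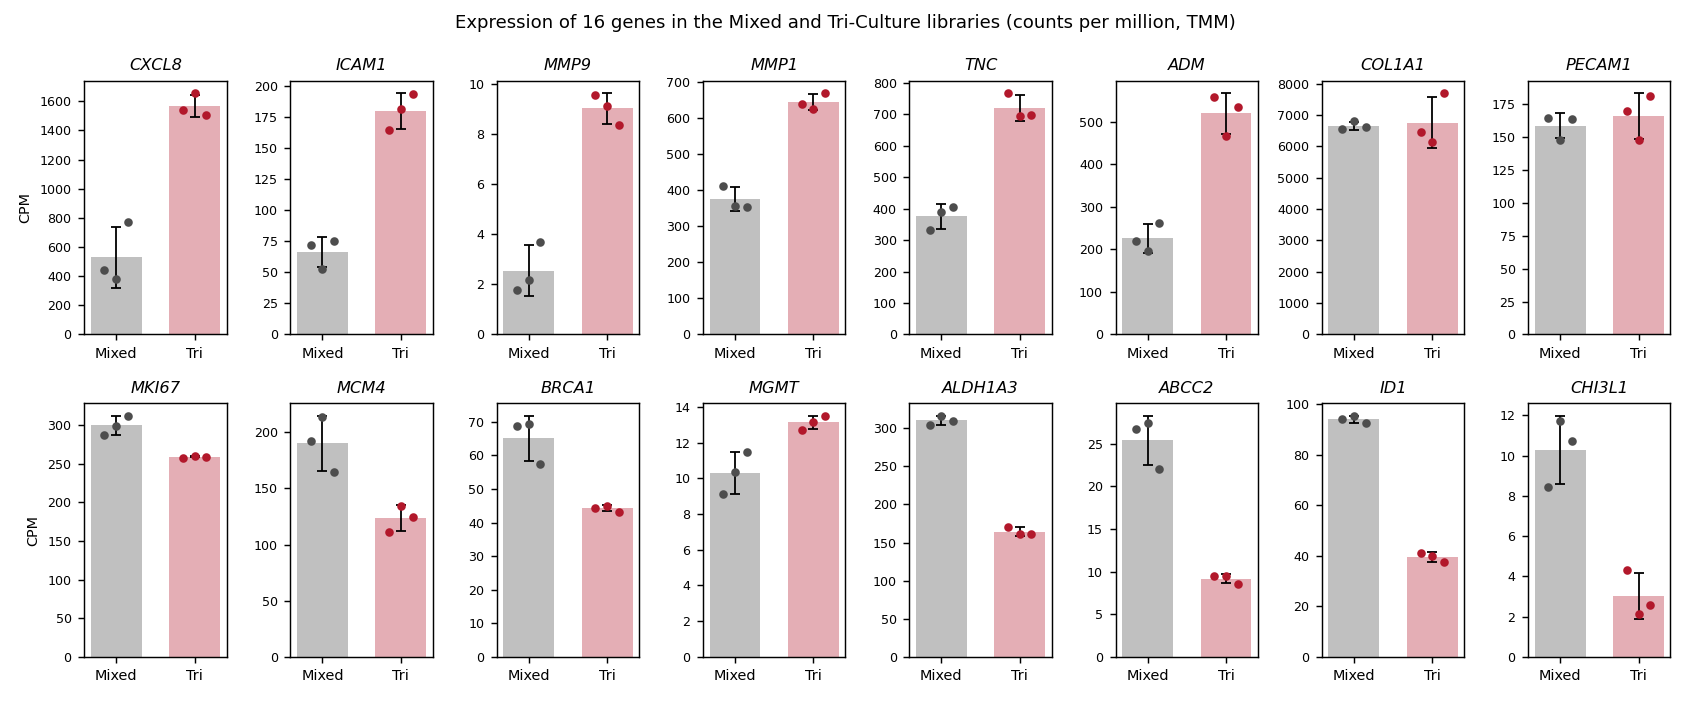
Expression of 16 genes in CPM (y axis, each panel with its own linear scale from 0) in Mixed (grey) and Tri-Culture (red). Points are libraries, bars are means and error bars are SD (n = 3). CXCL8, ICAM1, MMP1 and TNC are higher in all 3 Tri-Culture libraries than in any Mixed library, ALDH1A3, ABCC2 and ID1 are lower in all 3, and COL1A1 and PECAM1 overlap between the groups.

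Among 38 inflammatory cytokine and NF-kB target genes 12 were higher, 2 lower and 24 not past the threshold (15 and 2 adjusted over the list alone) and a median log2 fold change of 0.52. ICAM1, a leukocyte adhesion receptor, rose from 66.4 ± 12.01 to 179.8 ± 14.4 CPM (log2 1.44 ± 0.12). The cytokine IL32 (0.90 ± 0.10) and the NF-kB subunit RELB (0.90 ± 0.10) rose, and so did TNFAIP3, a brake on NF-kB (1.08 ± 0.16). CXCL8 was the most abundant of the risers at 1569 ± 77.8 CPM in Tri-Culture against 529.6 ± 211 in Mixed. CSF1, the macrophage growth factor, fell (−0.69 ± 0.11), and IL6 did not pass the test (0.86 ± 0.52, adjusted p = 0.321). The list passed camera (adjusted p = 2.149e-06) but not with an estimated correlation (adjusted p = 0.4655 with an estimated correlation). Mixed replicate 3 stood apart in this list: its members averaged 0.37 in log2, against −0.26 and −0.11 in the other Mixed libraries and 0.48 to 0.67 in Tri-Culture, and without that library 22 members were higher and 2 lower. Without Tri-Culture replicate 3 or Mixed replicate 2 only 7 were higher.

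Hypoxia and glycolysis genes showed the largest shift of any list, with a median log2 fold change of 0.71. Of the 41 members 19 were higher and none lower (28 and 0 adjusted over the list alone), and 40 had a positive change. ADM, the vasodilator peptide adrenomedullin, rose from 225.7 ± 33.9 to 519.8 ± 47.8 CPM (log2 1.20 ± 0.10). The stanniocalcins STC1 (0.86 ± 0.10) and STC2 (0.93 ± 0.09) rose, as did P4HA2, a subunit of collagen prolyl hydroxylase (0.76 ± 0.10), and the glucose transporters SLC2A1 (1.29 ± 0.20) and SLC2A3 (1.28 ± 0.16). GAPDH rose by 0.54 ± 0.08 on the log2 scale. VEGFA, the main angiogenic growth factor, stood at 1003 ± 190.2 CPM against 659.6 ± 120.1 and missed the threshold (0.60 ± 0.18, adjusted p = 0.0573), which it passed with DESeq2 (adjusted p = 7.802e-05) and without Mixed replicate 3 (adjusted p = 0.00387). HIF1A, which codes for an oxygen-regulated transcription factor controlled mainly at the protein level, had a log2 fold change of −0.17 ± 0.08 (adjusted p = 0.124), which passed with library totals alone (−0.29, adjusted p = 0.0172). The camera call (adjusted p = 2.209e-18) was lost with an estimated correlation (adjusted p = 0.4655 with an estimated correlation, estimate 0.706). The Mixed libraries were spread widely for these genes, at −0.335 in replicate 1, −0.005 in replicate 2 and 0.34 in replicate 3, against 0.62 to 0.95 in Tri-Culture. Without Mixed replicate 3, 35 members were higher, but only 14 were without Tri-Culture replicate 3 or without Mixed replicate 2.

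Many genes of matrix turnover changed in the shared gels. Among 36 matrix proteases, inhibitors and crosslinkers 17 were higher and 4 lower (20 and 5 adjusted over the list alone), with a median log2 fold change of 0.28. The interstitial collagenase MMP1 rose from 374.8 ± 33.3 to 645.5 ± 22.4 CPM (0.78 ± 0.08), and MMP19 (0.75 ± 0.08) and the aggrecanase ADAMTS4 (0.69 ± 0.08) rose too. MMP2, gelatinase A, did not pass (0.16 ± 0.06, adjusted p = 0.105). The 4 lower members were MMP3 (−0.74 ± 0.13), MMP16 (−0.52 ± 0.15), MMP15 (−0.42 ± 0.13) and the inhibitor gene TIMP4 (−0.63 ± 0.09), so the MMP genes moved both ways. The list passed camera (adjusted p = 2.149e-06) and fry (adjusted p = 0.033), but not camera with an estimated correlation (adjusted p = 0.4655 with an estimated correlation).

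Some collagens and other matrix genes rose as well, beside fibroblast markers with a median log2 fold change of 0.28, some of which are matrix genes themselves. Of 28 collagens 13 were higher and 2 lower (14 and 2 adjusted over the list alone; median 0.21). COL6A2 rose from 6142 ± 170.8 to 9342 ± 118.9 CPM (log2 0.60 ± 0.06), COL7A1, the anchoring fibril collagen, by 0.58 ± 0.07 and COL5A1 by 0.43 ± 0.07, whereas COL21A1 fell (−0.99 ± 0.17). COL1A1, the main fibrillar collagen, had nearly equal means, 6758 ± 827 CPM in Tri-Culture and 6655 ± 120.4 in Mixed (0.02 ± 0.08, adjusted p = 0.874). Of 47 glycoproteins, proteoglycans and hyaluronan genes 14 were higher and 2 lower (16 and 3 adjusted over the list alone; median 0.21). TNC, the matrix glycoprotein tenascin C, had the smallest p of them, with a rise from 374.9 ± 38.8 to 719.7 ± 40.9 CPM (0.94 ± 0.08). Rises were also seen in HSPG2, which codes for perlecan (0.71 ± 0.08), THBS2 (0.67 ± 0.08) and BGN, which codes for biglycan (0.51 ± 0.08). The hyaluronan receptor CD44 did not pass (0.08 ± 0.06, adjusted p = 0.396). Camera called both lists, with adjusted p = 0.00113 for collagens and 0.000209 for the glycoproteins, and neither held with an estimated correlation (adjusted p = 0.4655 for each with an estimated correlation). Only 8 of the glycoproteins were higher without Mixed replicate 2.

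Markers of the perivascular cell types changed in part. Of 25 fibroblast markers 10 were higher and none lower (13 and 1 adjusted over the list alone; median 0.28), although the mixes were set to hold an equal fraction of fibroblast RNA. FAP, a surface protease of activated fibroblasts, rose from 109 ± 7.84 to 166.3 ± 10.6 CPM (log2 0.61 ± 0.08). CCDC80 (0.40 ± 0.07), the transcription factor TWIST2 (0.72 ± 0.12) and the receptor PDGFRA (0.41 ± 0.09) rose as well. The list passed camera (adjusted p = 0.000209; adjusted p = 0.4655 with an estimated correlation). Of 35 endothelial markers 6 were higher and 3 lower (6 and 3 adjusted over the list alone; median 0.09, adjusted p = 0.432). EGFL7 (0.45 ± 0.11) and EMCN (0.42 ± 0.11) rose, and TMEM100 (−1.03 ± 0.18) and the connexin gene GJA4 (−0.60 ± 0.17) fell. No endothelial marker was higher and 3 were lower without Mixed replicate 2, and without Tri-Culture replicate 3 the counts were 1 and 1. PECAM1 (0.07 ± 0.08, adjusted p = 0.606), VWF (0.26 ± 0.09, adjusted p = 0.0684) and the VEGF receptor KDR (−0.23 ± 0.10, adjusted p = 0.129) did not pass. Among 12 lung mesenchyme transcription factors 4 were higher and 1 lower (4 and 1 adjusted over the list alone; median 0.09, adjusted p = 0.0699): TBX3 (0.78 ± 0.10), TBX4 (0.63 ± 0.10), FOXF2 (0.52 ± 0.09) and TBX5 rose, GATA6 fell (−0.73 ± 0.14), and TCF21 did not pass (0.04 ± 0.15). The list passed without Tri-Culture replicate 2 (adjusted p = 0.0202) or Mixed replicate 1 (adjusted p = 0.0478). Of 20 contractile and mural cell genes 4 were higher and 2 lower (5 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.215), with rises of CSPG4 (0.43 ± 0.07), NOTCH3 (0.58 ± 0.10) and KCNJ8 (0.56 ± 0.11) and a fall of MCAM (−0.34 ± 0.07). That list passed without Mixed replicate 1 (adjusted p = 0.0116). With library totals alone the medians of the endothelial and lung mesenchyme lists turned to −0.03 and −0.03, and both were −0.01 without Tri-Culture replicate 3. The lung mesenchyme median was 0.15 without Tri-Culture replicate 1 or 2.

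Of 41 angiogenic ligands, receptors and Notch genes 12 were higher, 1 lower and 28 not past the threshold (17 and 1 adjusted over the list alone; median 0.24). The Notch ligand DLL4 (0.53 ± 0.09), the Notch target HES1 (0.82 ± 0.17), the netrin receptor UNC5B (0.63 ± 0.11) and VEGFB (0.36 ± 0.08) rose. Camera called the list (adjusted p = 0.000166; adjusted p = 0.4655 with an estimated correlation). Without Mixed replicate 2 only 5 of its members were higher, and without Tri-Culture replicate 3 only 7.

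More than 0.5 of the cell cycle genes were lower in Tri-Culture. Of 45 G1/S genes 28 were lower and none higher (31 and 0 adjusted over the list alone; median −0.37), and of 56 G2/M genes 36 were lower and none higher (40 and 0 adjusted over the list alone; median −0.34). The replicative helicase subunits MCM4 (−0.62 ± 0.10) and MCM3 (−0.62 ± 0.10), the primase PRIM1 (−0.66 ± 0.12) and the DNA polymerase clamp PCNA (−0.52 ± 0.10) fell. So did the mitotic genes AURKA (−0.61 ± 0.08), HMMR (−0.64 ± 0.08), PLK1 (−0.59 ± 0.08) and CDC20 (−0.66 ± 0.09). MKI67, the proliferation marker Ki-67, fell from 299.6 ± 12.4 to 259 ± 1.01 CPM (−0.21 ± 0.06, adjusted p = 0.034), a call that was lost in 5 of the 6 fits that left out a library. Camera called both lists (adjusted p = 5.24e-12 for G1/S and 1.049e-14 for G2/M), and neither held with an estimated correlation (adjusted p = 0.4655 for each with an estimated correlation, at estimates of 0.697 and 0.512). Without Mixed replicate 2 the lower members numbered 13 in G1/S and 19 in G2/M, and without Tri-Culture replicate 1 those of G1/S numbered 16. Mixed replicate 3 averaged −0.167 for the G1/S genes, against 0.038 and 0.129 in the other Mixed libraries and −0.236 to −0.482 in Tri-Culture. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, held 0.0368, 0.0343 and 0.0363% of counts in Tri-Culture and 0.0278, 0.0276 and 0.0356% in Mixed.

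**Figure D2:**
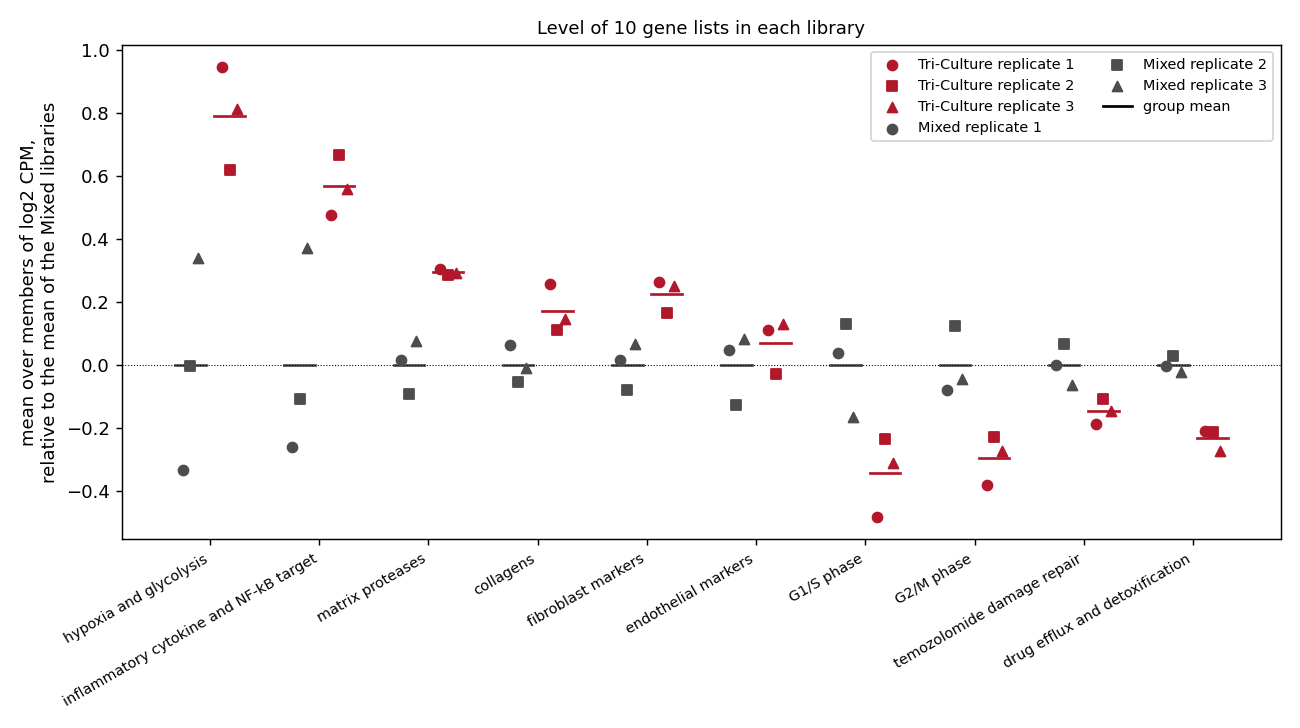
Level of 10 gene lists in each library, as the mean over tested members of log2 CPM relative to the mean of the Mixed libraries (y axis). Each symbol is one library (red Tri-Culture, grey Mixed, the shape gives the replicate) and horizontal lines are group means. Tri-Culture lies above Mixed for hypoxia and glycolysis (0.62 to 0.95 against −0.335 to 0.34) and below it for the G1/S and G2/M phases, and Mixed replicate 3 lies towards Tri-Culture in the first 2 lists.

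Genes that repair temozolomide damage were lower in part. Temozolomide is the alkylating drug used against glioblastoma, and the labels name no drug treatment of these gels. Of 35 members 9 were lower and none higher (10 and 1 adjusted over the list alone; median −0.18). BRCA1 fell from 65.1 ± 6.76 to 44.2 ± 0.90 CPM (log2 −0.56 ± 0.08), and RAD51C (−0.59 ± 0.11) and PARP1 (−0.40 ± 0.09) fell. The mismatch repair gene MSH6 (−0.31 ± 0.08, adjusted p = 0.0168) fell too, but lost its call in 4 of the 6 fits that left out a library. MGMT, whose product removes the O6-methylguanine left by temozolomide, lay at 13.1 ± 0.39 CPM in Tri-Culture and 10.3 ± 1.18 in Mixed and just missed the threshold (0.35 ± 0.12, adjusted p = 0.0505), with an adjusted p of 0.033 without Mixed replicate 3 and 0.0363 by DESeq2. Camera called the list (adjusted p = 0.00238; adjusted p = 0.4655 with an estimated correlation). Without Mixed replicate 2 only 4 members were lower, and without Tri-Culture replicate 3 only 5.

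Drug efflux and detoxification genes changed mostly downwards, with 12 of 30 lower and 3 higher (15 and 4 adjusted over the list alone; median −0.23). ALDH1A3, a retinaldehyde dehydrogenase used as a marker of mesenchymal glioma stem cells, fell from 310.1 ± 6.39 to 164.2 ± 5.54 CPM (log2 −0.92 ± 0.06). The efflux pump ABCC2 (−1.47 ± 0.11), the aldose reductase AKR1B1 (−0.74 ± 0.09) and the quinone reductase NQO1 (−0.64 ± 0.09) also fell. ABCB1, the pump P-glycoprotein, was of low abundance at 0.688 ± 0.168 and 0.563 ± 0.289 CPM and did not differ detectably (adjusted p = 0.691). The list passed camera (adjusted p = 2.221e-05) and fry (adjusted p = 0.033), but not camera with an estimated correlation (adjusted p = 0.4655 with an estimated correlation).

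Glial and glioblastoma markers moved both ways. Of 26 members 20 could be tested, and 5 were higher and 2 lower (6 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.209). The higher members numbered 3 without Tri-Culture replicate 2 or 3 or without Mixed replicate 1 or 2. TNC and the growth factor receptor gene EGFR (0.50 ± 0.10) rose, and CHI3L1 and SOX9 (−0.96 ± 0.17) fell. IL13RA2, an interleukin 13 receptor abundant in glioblastoma, had 28 ± 0.73 against 23.4 ± 2.16 CPM (0.26 ± 0.09, adjusted p = 0.0599), and NES, which codes for nestin, did not pass (−0.04 ± 0.07). SOX2 held 0 to 5 counts per library. It fell below the low-count filter, as did PTPRZ1, GFAP (0 to 15 counts), S100B, NCAN and DCX, which need not mean that they are silent. The list was tested without these genes, and the changes of its other members cannot be assigned to U87-MG. Of 28 glioma stem cell and invasion genes 8 were higher and 6 lower (8 and 6 adjusted over the list alone). The higher members numbered 2 without Mixed replicate 2, 3 without Tri-Culture replicate 1 or 3, and 4 or 5 without Mixed replicate 1 or Tri-Culture replicate 2. RUNX1 (0.60 ± 0.08) rose, while ID1, a transcription inhibitor induced by BMP signalling, fell from 94 ± 1.52 to 39.5 ± 1.87 CPM (−1.25 ± 0.07), the smallest p among list members. The median of that list was 0.11, its mean −0.03 and its camera direction down (adjusted p = 0.644). Of the 3 genes of the 9p21 interval, which U87-MG lacks, CDKN2B fell (−0.57 ± 0.14; 1 lower and 0 higher adjusted over the list alone), and CDKN2A (0.07 ± 0.12) and MTAP (0.16 ± 0.12) did not pass. Here the median was 0.07, the mean −0.11 and the camera direction down (adjusted p = 0.635), and the median turned to −0.04 with library totals alone and −0.07 without Mixed replicate 2. No gene of the interval was called without Tri-Culture replicate 2.

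TGF-beta response genes passed camera upwards (adjusted p = 0.0271; adjusted p = 0.4655 with an estimated correlation), with 6 of 28 higher and 2 lower (10 and 2 adjusted over the list alone; median 0.29). TGFB1 (0.38 ± 0.07) and INHBA, which codes for an activin subunit (1.26 ± 0.18), rose, whereas ID1 and the latent TGF-beta binding protein gene LTBP3 (−0.48 ± 0.08) fell. The camera call ended without Mixed replicate 2 (adjusted p = 0.0942), and without Mixed replicate 1 the higher members numbered 10. Interferon-stimulated genes passed downwards (adjusted p = 0.00308; adjusted p = 0.6434 with an estimated correlation), with 5 of 42 lower and none higher (5 and 0 adjusted over the list alone; median −0.23). They included IFI44L (−0.84 ± 0.08), PARP9 (−0.54 ± 0.11) and IFI35 (−0.55 ± 0.14). The Mixed libraries ranged from −0.295 to 0.279 for these genes, and the call ended without Mixed replicate 3 (adjusted p = 0.156), while 11 members were lower without Mixed replicate 1, 9 without Tri-Culture replicate 1 and 3 without Tri-Culture replicate 3 or Mixed replicate 2.

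Of 60 ribosomal protein genes 15 were higher, none lower and 45 not past the threshold (24 and 0 adjusted over the list alone; median 0.17), among them RPL5 (0.25 ± 0.06), RPL12 (0.24 ± 0.06), RPS6 (0.25 ± 0.06) and RPS27 (0.30 ± 0.08). Camera called the list (adjusted p = 4.533e-05; adjusted p = 0.6434 with an estimated correlation). With library totals alone its median was 0.06 and the named members lost their calls, no member was called without Tri-Culture replicate 3, and only 4, 5, 7 and 8 were without Tri-Culture replicate 2 and Mixed replicates 1, 2 and 3. Of 34 oxidative phosphorylation genes 6 were lower, none higher and 28 not past the threshold (4 and 0 adjusted over the list alone; median −0.12), including NDUFB3 (−0.35 ± 0.08), ATP5F1B (−0.29 ± 0.08), NDUFA9 (−0.32 ± 0.09) and ATP5MC1 (−0.32 ± 0.09). That list passed camera (adjusted p = 0.00461; adjusted p = 0.7225 with an estimated correlation) except without Mixed replicate 2 (adjusted p = 0.0942), where no member was called, and only 1 member was called without Tri-Culture replicate 1 or 3.

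The remaining lists did not pass camera. Of 25 immediate early and heat shock genes 5 were higher and 6 lower (7 and 6 adjusted over the list alone; median 0.16, adjusted p = 0.54): the nuclear receptors NR4A3 and NR4A1 (0.94 ± 0.20) rose, and the chaperones HSPH1 (−0.75 ± 0.10) and DNAJA1 (−0.50 ± 0.10) fell. Without Mixed replicate 2 the counts of that list were 2 and 2, without Tri-Culture replicate 3 they were 3 and 5, and without Mixed replicate 3 they were 9 and 6. Of 26 cholesterol synthesis genes 2 were higher and 4 lower (2 and 4 adjusted over the list alone; median −0.13, adjusted p = 0.138), with a fall of EBP, a sterol isomerase (−0.40 ± 0.12), and rises of SREBF2 (0.33 ± 0.08) and STARD4 (0.40 ± 0.10). That list passed without Mixed replicate 1 (adjusted p = 0.00105, 8 members lower), while only 1 member was lower without Tri-Culture replicate 1 or 2 or Mixed replicate 2. Of 30 unfolded protein and amino acid stress genes 3 were higher and 3 lower (3 and 3 adjusted over the list alone; median 0.22, adjusted p = 0.1), among them PPP1R15A (0.65 ± 0.12), the chaperone gene HSP90B1 (0.51 ± 0.11), PDIA4 (0.34 ± 0.08) and ATF5 (−0.41 ± 0.09). It passed without Tri-Culture replicate 2 (adjusted p = 0.018), Tri-Culture replicate 3 (adjusted p = 0.00478) or Mixed replicate 3 (adjusted p = 0.0189, 6 members higher), but had an adjusted p of 0.972 and a median of 0.08 without Tri-Culture replicate 1. That library averaged 0.452 for these genes, against 0.052 and 0.047 in the other Tri-Culture libraries. Only 1 member of the list was lower without Tri-Culture replicate 3 or Mixed replicate 2. Of 26 p53 targets 3 were higher and 1 lower (3 and 1 adjusted over the list alone; median 0.07, adjusted p = 0.505). The cell cycle inhibitor gene CDKN1A (0.26 ± 0.07), DDB2 (0.40 ± 0.09) and GDF15 (0.56 ± 0.13) rose and TIGAR, a regulator of glycolysis, fell (−0.57 ± 0.09). No p53 target was higher and 1 was lower without Mixed replicate 2, and with library totals alone the median of the list was −0.04.

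Markers of cell types that were not seeded were tested in part only. The others fell below the low-count filter, which need not mean that they are silent. Of 21 epithelial markers 8 could be tested and none changed (0 and 0 adjusted over the list alone; adjusted p = 0.584), but 2 were higher without Mixed replicate 3. The Mixed libraries were spread from −0.539 in replicate 1 to 0.666 in replicate 3 for these markers. Of 10 tested leukocyte markers 2 were higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.22, a mean of 0.11 and a camera direction of down (adjusted p = 0.899). LAPTM5 (0.44 ± 0.12) and the lysosomal gene CD68 (0.25 ± 0.08) rose, CD68 from 369.1 ± 39.7 to 440 ± 14.1 CPM. No leukocyte marker was higher without Tri-Culture replicate 3 or Mixed replicate 2. CD74, the invariant chain of MHC class II, which stimulated endothelial cells and fibroblasts also express, fell from 220 ± 29.2 to 104.6 ± 6.34 CPM (−1.07 ± 0.09).

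**Figure D3:**
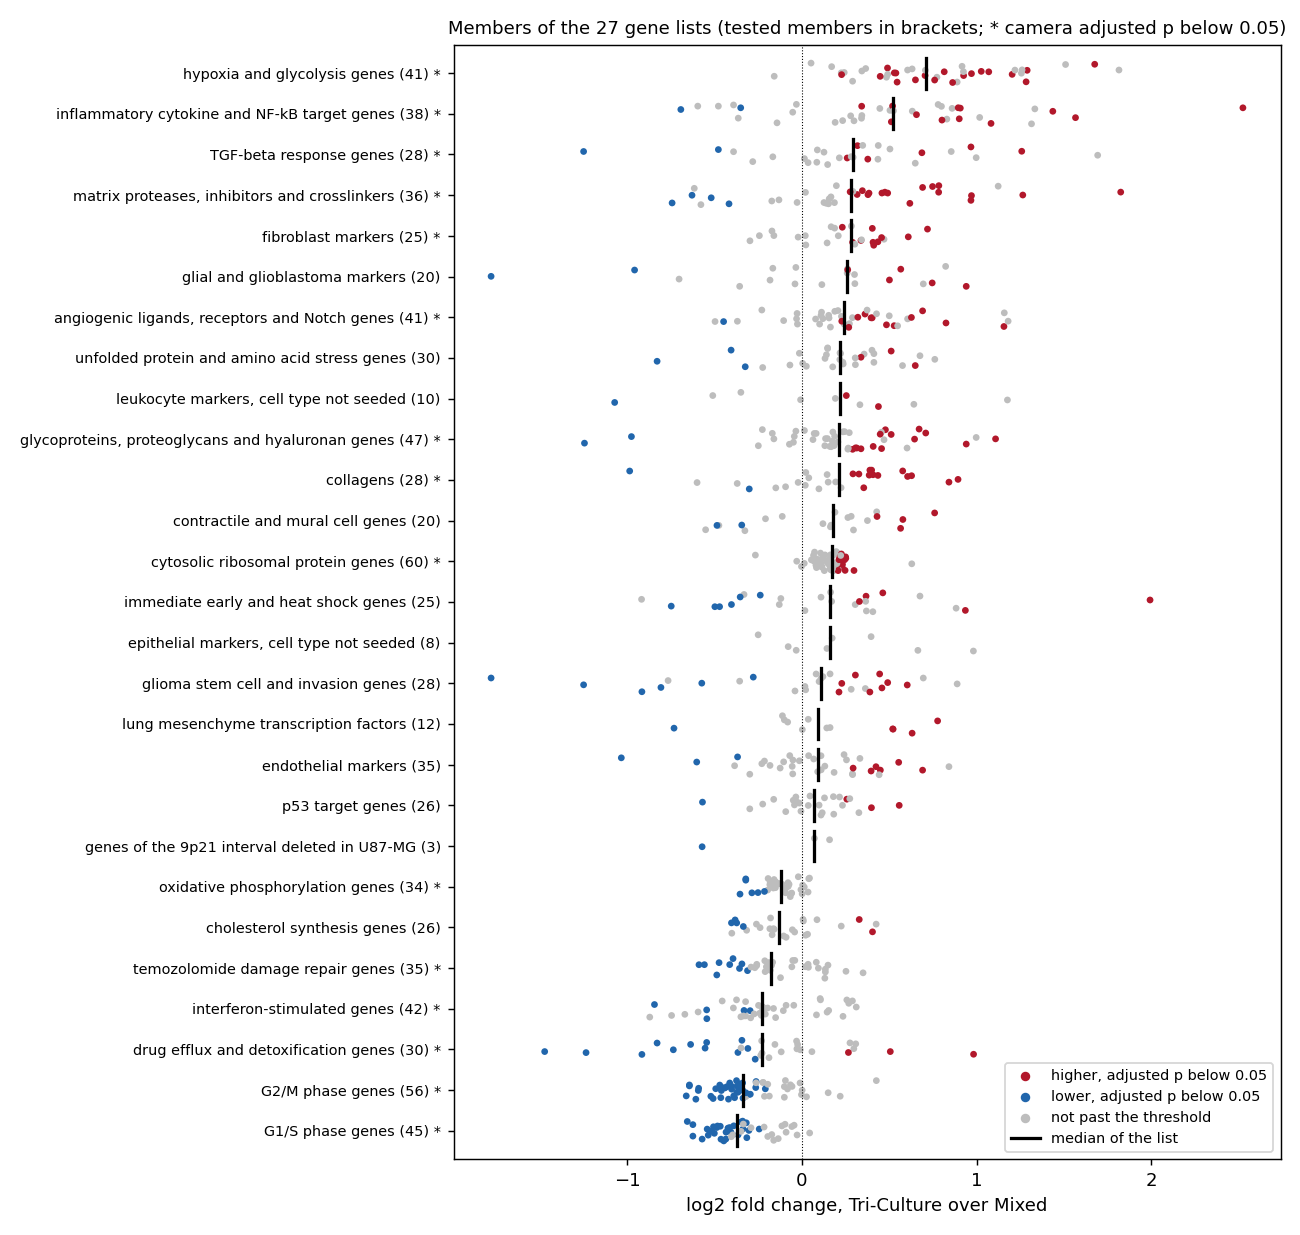
Log2 fold change of Tri-Culture over Mixed (x axis) for the tested members of the 27 gene lists (y axis, ordered by median). Each point is a gene (red higher and blue lower at an adjusted p below 0.05, grey not past the threshold), black bars are list medians, and asterisks mark lists called by camera with the preset correlation. Medians run from −0.37 for G1/S genes to 0.71 for hypoxia and glycolysis genes.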

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

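The leave-out of genes on alternate scaffolds was chosen after seeing the data, and the other alternatives before. Gene counts stayed close under DESeq2's size factors, no low-count filter, DESeq2's Wald test (1938 higher, 1936 lower) and without genes on alternate scaffolds (1754 higher, 1674 lower). Library totals alone gave 1068 higher and 3344 lower genes, since that scaling moves the median of all genes by −0.11, and all 1681 genes lower under TMM were among the latter. The stricter filter, which tests fewer genes, left 155 genes higher by a fold of at least 2. Leaving out one library gave 742 to 1867 higher genes, 695 to 1883 lower genes, 110 to 416 higher and 117 to 194 lower by a fold of at least 2, and 8 to 11 lists higher and 5 to 7 lower. The lowest gene counts came without Mixed replicate 2 and the highest without Mixed replicate 3, and the cause was not tested. Of the 742 genes higher without Mixed replicate 2, 734 were also higher with all libraries. With an estimated correlation 0 lists were higher and 0 lower, and fry called 1 each way.

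Same-numbered libraries did not deviate together (r across genes of −0.002, 0.068 and −0.049), so the numbers were not taken to pair the samples. With the replicate number as a block 1912 genes were higher and 1803 lower, 230 and 161 by a fold of at least 2, and 10 lists higher and 6 lower. Not every library correlated best with its own number.

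Of 116 called named genes 31 lost the call under an alternative other than the block, and none changed sign. Signs turned only for genes that had not passed. Library totals shift all genes by −0.114, and that shift alone turned PECAM1 (−0.048), COL1A1 (−0.093), TCF21 (−0.077), CDKN2A (−0.041) and CD44 (−0.033). Leaving out one library, where the cause was not tested, gave −0.001 to 0.146 for PECAM1, −0.082 to 0.087 for COL1A1, −0.103 to 0.202 for TCF21, −0.094 to 0.022 for NES, −0.068 to 0.178 for CDKN2A and −0.098 to 0.592 for ABCB1. Of the lists, 3 that were not called turned direction, at adjusted p of 0.0889 to 0.811 for endothelial markers, 0.203 to 0.9997 for glioma stem cell genes and 0.579 to 0.9997 for leukocyte markers. Of 15 called lists, 3 lost the call when a library was left out. The simulated test recovered 49% of changes of 0.5 in log2 over all tested genes and 71% at a mean CPM of 5 or more.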

Other observations

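The gene families in this paragraph were picked after their values were seen. Toll-like receptor genes moved in opposite directions: of 7 tested, TLR1 (−0.99 ± 0.29), TLR3 (−1.31 ± 0.23), TLR4 (−1.18 ± 0.18) and TLR6 (−1.02 ± 0.17) were lower in Tri-Culture, and TLR2, which senses bacterial lipoproteins as a partner of TLR1 or TLR6, rose from 8.22 ± 0.98 to 20.6 ± 2.66 CPM (log2 1.33 ± 0.13, SE, n = 3). TLR5 and TLR9 did not pass. Genes of the MHC class II pathway outside the HLA genes fell in 4 of 8 cases: the class II transactivator CIITA (−1.54 ± 0.22), CD74 (−1.07 ± 0.09), the thiol reductase IFI30 (−0.88 ± 0.10) and RFX5 (−0.47 ± 0.08), while the protease gene CTSS rose from 26.9 ± 5.47 to 50.8 ± 8.26 CPM (0.92 ± 0.16). Both adenosine receptor genes that could be tested fell, ADORA2B from 26.2 ± 2.69 to 12.2 ± 0.83 CPM (−1.11 ± 0.11) and ADORA1 by less abundant counts (−1.34 ± 0.31). Of 28 semaphorin and plexin genes 7 were higher and 3 lower: SEMA4B (1.21 ± 0.20), SEMA4D (1.03 ± 0.24) and SEMA5A (0.57 ± 0.07) rose, and SEMA3B (−1.01 ± 0.18), PLXNA4 (−0.94 ± 0.17) and PLXNA2 (−0.73 ± 0.10) fell. Among 8 Wnt ligand genes WNT5A rose from 281.6 ± 16.9 to 369.6 ± 17.3 CPM (0.39 ± 0.07), WNT5B (0.38 ± 0.11) and WNT11 rose, and none fell. Of 8 metallothionein genes MT3 (1.52 ± 0.18), MT2A (0.46 ± 0.10) and MT1G (0.67 ± 0.18) rose. The called members named here kept their direction with library totals alone.

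The comparisons of scaling and of the fibroblast and endothelial share were chosen after related values had been seen. So was that of genes higher against genes lower in Mixed replicate 3. The other tests were chosen before their values were seen. Mixed replicate 3 itself was picked because the first principal component set it apart. The lower cell cycle genes may come from a smaller share of the tumour line's RNA in Tri-Culture. Cancer-testis antigen genes, which normal somatic cells silence and tumour lines can transcribe, would then fall at least as far. The 4 that could be tested were CTAG2, MAGEC1, MAGEC2 and SSX1. Their median log2 fold change was 0.21, against −0.35 for 101 cell cycle members. The difference was 0.56 (95% bootstrap interval 0.10 to 0.98, with the fit error of each gene included). That goes against the explanation but does not exclude it. The 4 genes are of low abundance in families with similar copies. The interval also draws genes as if independent, although the G1/S genes had an estimated correlation of 0.697. A scaling error moves all genes alike, so it cannot alter how far the cell cycle members lay below all tested genes. That distance was a median of −0.36 (95% bootstrap interval −0.40 to −0.30, with genes drawn as if independent). It restates the fall already seen and is not a separate test of scaling. Slower division of any of the 3 cell types in the shared gel stays open and was not tested.

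The higher hypoxia and glycolysis genes could come with a larger share of fibroblast or endothelial RNA, since fibroblast markers rose too. The hypoxia members exceeded the larger of the marker medians by 0.42 (95% bootstrap interval 0.23 to 0.67). That interval draws genes as if independent, whereas their estimated correlation was 0.706, so it leaves out spread shared between libraries. It is too narrow to exclude a larger share of either cell type. A larger share of U87-MG RNA was not tested. The median of the hypoxia members stayed at 0.59 or more under the other scalings, so those scalings did not remove the rise. No biological explanation was tested.

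Mixed replicate 3 lay between the groups on the first principal component and in the hypoxia, inflammatory and G1/S lists. If Tri-Culture RNA had entered that library, one mixing share would place all changed genes at the same point between the other Mixed libraries (0) and Tri-Culture (1). On genes called without that library, the median position was 0.41 for 35 hypoxia and glycolysis genes and 0.46 for 1731 genes lower in Tri-Culture, a difference of −0.04 (95% bootstrap interval −0.13 to 0.04). Genes higher in Tri-Culture lay at 0.28 (1554 genes), which is 0.18 below the genes lower (−0.20 to −0.15). One mixing share alone would give no gap. However, the genes were called with the same Mixed libraries that set the point 0. That choice can itself move Mixed replicate 3 towards Tri-Culture, and not equally for genes higher and lower. No other library was placed in this way for comparison, so the gap does not decide the question. With library totals alone the positions were 0.35 and 0.41, a gap of −0.06 (−0.09 to −0.04), so its size depends on the scaling. The intervals of these positions also draw genes as if independent and leave out spread that genes share between libraries. Interferon-stimulated genes did not lie between the groups in this library, at 0.279 against −0.083 to −0.309 in Tri-Culture and −0.295 and 0.016 in the other Mixed libraries, which admixture alone would not give. Whether Tri-Culture RNA entered the library is therefore left open, as is the alternative that its gels were themselves closer to the Tri-Culture state.

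The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3455 changed genes, and 1 split (the real one) gave as many; the highest other count was 0. For changes of at least 2-fold the real count was 416, reached by 1 split, with a highest other count of 0. For gene lists the real count was 15, and 3 splits gave as many, the highest other count being 19. Each other split keeps 2 libraries of one culture on each side, and the split with 19 lists puts Mixed replicate 3 with Tri-Culture replicates 1 and 3.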
